A study of Pseudomonas aeruginosa PAO1 with 4 samples.

How the data were processed

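RNA was measured in 4 libraries of Pseudomonas aeruginosa PAO1, 2 from untreated cultures and 2 from cultures exposed to S100A12, and the groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with an NEBNext Ultra kit, and the S100A12 protein carried a histidine tag and was purified on a nickel column. The authors deposited a table of whole-number read counts per gene, not normalised, which was used as the unit of analysis. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0.316, FastQC 0.11.9, MultiQC 1.9, fastp 0.20.1, Bowtie2 2.1.0 and featureCounts 2.0.1. The strand setting, the treatment of reads that map to several places and the genome build were not given in the sources used here. Reads of near-identical copies, such as the phz1 and phz2 operons and the ribosomal RNA operons, and of overlapping or antisense genes are therefore uncertain. A bias from read mapping or rRNA removal cannot be undone from the counts.

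All 5678 locus tags matched the RefSeq gene table of assembly ASM676v1, and 1766 had a symbol other than the locus tag. That table was used for names, RNA classes and the order of neighbouring genes, and no coordinates are given. The 4 columns were assigned to samples by their names.

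Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling and filterByExpr with default settings, which removed 0 genes. Groups were compared with edgeR's quasi-likelihood test, with no covariate and 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. All tests were two-sided except the Fisher tests of gene-name families, which were one-sided. Log2 fold changes are treated over untreated, and levels are normalised CPM. The biological coefficient of variation was 12.5%. Total counts ran from 32541118 to 44054490, and the lowest count of any gene was 23, so counting error was small beside the spread between replicates for most genes. Counts without molecular identifiers are not independent molecules, so depth speaks to counting error only. With 2 libraries against 2, an exact permutation test cannot reach 0.05.

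The 28 gene lists, the tests of genes and of lists and the alternatives were fixed before the data were examined, while some tests of possible causes, of gene families and of neighbouring genes were chosen later. Lists held 679 memberships, of which 4 had no row used here. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. Of 14 lists called with the preset correlation, 0 were called with an estimated correlation and 1, denitrification and arginine fermentation, with fry. The estimated correlations of these 14 lists ran from 0.10 for denitrification and arginine fermentation to 0.86 for the Pf prophage. The preset value thus treats genes of a list, many of them operon neighbours, as nearly independent. The estimates in turn rest on 2 residual degrees of freedom, so neither set of list p-values can be taken as exact. The genes named were, by a rule fixed in advance, the 8 largest changes per direction among called genes with groups that did not overlap and a mean of at least 10 CPM, the 4 members with the lowest p of each list that was called or had at least 3 members called, the 1 with the lowest p of each other list, and znuA, cntO, czcA, pvdS, oprH and rpoS. Genes outside that rule are said to have been chosen after their values were seen.

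The alternatives were median-of-ratios size factors, upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no count filter, a minimum of 10 CPM in 2 libraries, ribosomal and transfer RNA genes left out, the replicate number as a block, an adjusted p of 0.01, a minimum change of 2-fold, and each library left out in turn. The steps were tested on simulated data with the real genes' means and library sizes and changed genes of known fold. For the comparison of treated with untreated over 5678 genes, edgeR recovered 68.7% of simulated 1.5-fold changes, 95.5% of 2-fold changes and 100% of 4-fold changes, and 2.76% of its calls were false. DESeq2 recovered 70.1%, 95.5% and 98.5%, with 7.85% of calls false. The simulation changed only 67, 67 and 66 genes by 1.5-, 2- and 4-fold. It drew each gene independently, with no shift shared by genes of a library. The shares recovered and false therefore hold for such data only and do not give the share of false calls in the real comparison. Figures and tables were made with Python 3.11.15, and no check of base composition or gene length was made.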

Results

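RNA was sequenced from cultures of Pseudomonas aeruginosa PAO1, the reference laboratory strain of this opportunistic pathogen, with and without the human protein S100A12. S100A12, also called calgranulin C, is a calcium-, zinc- and copper-binding protein that neutrophils release at sites of infection. Bacteria were pregrown for 2 h, and a starting optical density of 0.2 was given. Cultures of 1000000 colony-forming units were then incubated for 6 h, either with 500 µg/ml of the purified protein or untreated. The data held 2 untreated and 2 S100A12-treated libraries, with a read count for each of 5678 genes. Total counts were 36078646 and 32541118 in untreated replicates 1 and 2, and 38189315 and 44054490 in treated replicates 1 and 2. No gene had a count of 0 in any library, and the lowest counts were 55, 60, 23 and 26 in the same order. Ribosomal RNA genes took 15.3% of the counts of untreated replicate 1, 4.37% of untreated replicate 2, 8.5% of treated replicate 1 and 6.91% of treated replicate 2. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 445 for the untreated pair and 51.7 for the treated pair. These values include the ribosomal RNA genes, whose shares lay far apart in the untreated pair (15.3% and 4.37%). They therefore do not compare the spread of other genes between the pairs. Pearson's r of log2 CPM (counts per gene scaled to the size of the library) across genes, which are not independent replicates, was 0.988 within the untreated pair and 0.994 within the treated pair. Between the groups it lay from 0.944 to 0.963.

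The design asks how the transcriptome of PAO1 differs after exposure to S100A12. The genes that rose most were those of denitrification, the use of nitrogen oxides in place of oxygen for respiration. PA0525, a norD-like gene beside the nitric oxide reductase genes, went from 70.9 ± 5.24 to 595 ± 47.1 normalised CPM (mean ± SD, n = 2), a rise of 8.39-fold. The nitrite reductase gene nirS rose from 893 ± 41.2 to 4812 ± 691, and the nitric oxide reductase gene norB from 405 ± 11.3 to 2307 ± 213 normalised CPM. The genes that fell most included PA3931, from 235 ± 2.99 to 29.0 ± 7.87 normalised CPM, and the type VI secretion sheath gene PA0084, from 2291 ± 351 to 399 ± 41.4. The other genes with the largest rises were nosF, nirC, nirM, PA0510 and nosZ, all of denitrification clusters, with log2 fold changes from 2.45 to 2.90. Beside PA3931 and PA0084, the largest falls were those of PA0284 (log2 fold change -2.66), PA0083 (-2.36), PA1845 (-2.30), hcp1 (-2.24), PA3450 (-2.17) and PA2204 (-2.12). PA0083, PA1845 and hcp1 belong to type VI secretion, PA0284 neighbours the sulfate-binding protein gene sbp, and PA3450 encodes a peroxiredoxin.

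Of the 5678 genes tested, 2064 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1026 higher and 1038 lower in the treated cultures. The change was at least 2-fold for 349 of them, 156 higher and 193 lower. The treated and untreated libraries did not overlap for 2044 of the called genes, which calling itself favours. They did not overlap for 69.0% of all genes, against a chance of 33.3% for a single gene. Genes in the same 4 libraries vary together, so this share is not a test of the treatment. Scaling by library totals alone gave 1142 calls, 452 higher and 690 lower, so that 39.6% of calls were higher against 49.7% with TMM scaling. The count was 1158 without untreated replicate 1, 965 without treated replicate 1 and 1328 without treated replicate 2. The labels do not say whether replicates were separate cultures, so the spread between libraries that p-values measure may be technical. That spread was mostly pooled over genes, with a weight of 39.3 degrees of freedom against 2 from a gene's own libraries.

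**Figure D1:**
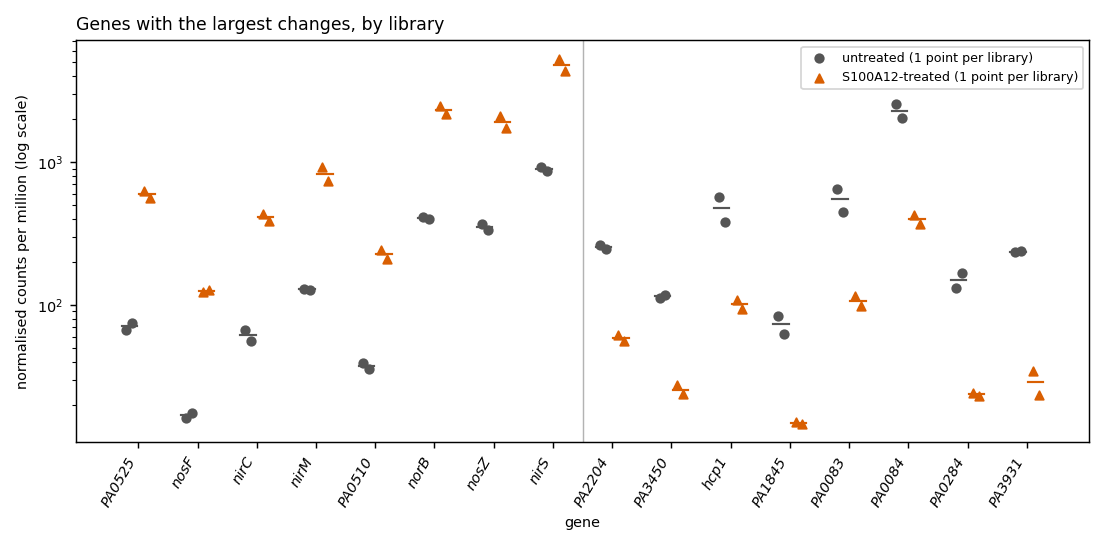
Normalised CPM (log scale) of the 8 genes with the largest rise (left of the line) and the 8 with the largest fall (right), with 1 point per library and a short bar at each group mean. The treated libraries lie apart from the untreated ones for all 16 genes, as the rule of choice required, for nirS at a mean of 4812 against 893 and for PA3931 at 29.0 against 235.

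Most genes listed for growth without oxygen rose. Of the 30 genes in the list of denitrification and arginine fermentation, 22 rose, 2 fell and 6 did not pass the test, with a median log2 fold change of 1.5. The nitrous oxide reductase genes nosZ (log2 fold change 2.45 ± 0.16 SE) and nosF (2.90 ± 0.13) rose with the nitrite reductase genes nirS (2.43 ± 0.18) and nirC (2.73 ± 0.13). Chosen after their values were seen, the arginine deiminase genes arcA, arcB, arcC and arcD, which yield ATP from arginine, rose by log2 values of 1.54, 1.37, 1.5 and 1.10. The nitrate transporter genes narK1 (-1.57) and narK2 (-0.74), chosen in the same way, were the 2 that fell, although narH, narI and narJ of the same respiratory nitrate reductase locus rose and narG had a value of 0.22 with an adjusted p of 0.262. Without treated replicate 2, narH (0.31, adjusted p 0.0949) and narI (0.37, adjusted p 0.157) lost their calls, narJ was at 0.72 and narG was negative (-0.18, adjusted p 0.381). Without treated replicate 1, narG was called higher (0.54, adjusted p 0.0421). The list was called by camera with an adjusted p of 1.26e-37, and had an adjusted p = 0.486 with an estimated correlation between its genes, and adjusted over the list alone the counts were again 22 and 2.

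Type VI and type III secretion moved in opposite directions. All 21 genes of the H1 type VI secretion list, a contractile apparatus that injects toxins into competing bacteria, fell, with a median log2 fold change of -1.58. The inner tube gene hcp1 went from 478 ± 134 to 101 ± 11.1 normalised CPM (mean ± SD, n = 2), and the sheath genes PA0083 and PA0084 fell by 2.36 and 2.52 on the log2 scale. Of the 40 genes for type III secretion, the needle complex that delivers toxins into host cells, 21 rose, 1 fell and 18 did not pass the test, with a median log2 fold change of 0.32. PA1700 (1.54 ± 0.14 SE), pcrG (1.22 ± 0.17) and pscP (0.98 ± 0.12) of the apparatus rose, and so did the toxin genes exoS (0.42) and exoT (0.50), which were chosen after their values were seen. The member that fell was exsA, the transcriptional activator of the system, at -0.31, also chosen after its value was seen.

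The type VI list was called by camera with an adjusted p of 1.68e-45, which was an adjusted p = 0.528 with an estimated correlation. For type III secretion camera gave an adjusted p of 1.41e-05, and an adjusted p = 0.866 with an estimated correlation. The counts adjusted over the list alone were 21 type VI genes lower, and 22 type III genes higher with 1 lower. The count of type III genes called higher was 12 without treated replicate 1 and 13 with library totals alone, and 0 were called lower without untreated replicate 1, without either treated library, with library totals alone, with DESeq2 or with limma-voom. exoS lost its call with any single library left out (adjusted p 0.0525 to 0.272), and exoT without treated replicate 1 (0.13) and without untreated replicate 2 (0.135).

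Most pyoverdine genes fell, and other iron-repressed genes fell more often than they rose. Of 21 genes for pyoverdine, the main siderophore, 15 fell, 0 rose and 6 did not pass the test, with a median log2 fold change of -0.75. The iron-starvation sigma factor gene pvdS went from 203 ± 17.6 to 60.4 ± 0.796 normalised CPM (mean ± SD, n = 2), and pvdE (-1.43 ± 0.12 SE), an exporter of the precursor, also fell. Of 26 genes for heme uptake, ferrous iron and other iron-repressed functions, 14 fell, 5 rose and 7 did not pass the test, with a median of -0.41. The heme receptor gene phuR (-1.50 ± 0.14), the siderophore receptor gene pirA (-1.14 ± 0.12) and the manganese superoxide dismutase gene sodM (-0.96) fell. The 5 that rose, named after their values were seen, were PA4357 (0.69), PA4358 (0.50) and PA4359 (0.94) of the ferrous iron transporter Feo, with exbB1 (0.54) and exbD1 (0.68) of an energy-transducing complex. PA4359 and exbD1 stayed called with each library left out, PA4357 and PA4358 lost the call without untreated replicate 2 or treated replicate 1, and exbB1 lost it in each case.

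The pyoverdine list had an adjusted p of 2.65e-15 by camera and an adjusted p = 0.528 with an estimated correlation. The heme and iron list had an adjusted p of 3.81e-04 by camera and an adjusted p = 0.866 with an estimated correlation, and its count of falls was 8 without treated replicate 1. Its count of rises was 2 without untreated replicate 2, without treated replicate 1, or with library totals alone. Of 14 genes for pyochelin, the other siderophore, 3 fell and 2 rose, among them the regulator gene pchR (-0.77) and the transporter gene PA4222 (0.75). Falls numbered 1 without untreated replicate 1 or treated replicate 1 and 2 without treated replicate 2, and rises 4 without untreated replicate 1 and 1 without each other library, with DESeq2, with limma-voom, with upper-quartile factors or with library totals alone. That list was not called by camera (adjusted p 0.948), and its median of 0.06 had the opposite sign to its mean of -0.01 and to the direction of the test. Adjusted over the list alone, 15 pyoverdine genes fell, 15 heme and iron genes fell and 5 rose, and 3 pyochelin genes fell and 2 rose.

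Genes that zinc represses through the regulator Zur fell more often than they rose. Of 33 such genes, 14 fell, 4 rose and 15 did not pass the test, with a median log2 fold change of -0.26. PA4064, a transporter gene, went from 290 ± 23.6 to 138 ± 7.14 normalised CPM (mean ± SD, n = 2), and PA3600 (-0.73) and PA3601 (-0.93), which encode ribosomal proteins that do without zinc, fell. PA4837 (-0.71) and PA4834 (-0.75), the cntO receptor and the exporter of the metallophore pseudopaline, fell as well. PA5498, the zinc-binding protein gene znuA, had a log2 fold change of 0.08 ± 0.10 SE and an adjusted p of 0.589, so no difference was detected. The 4 that rose, named after their values were seen, were PA1923 (0.28), np20 (0.32), PA2439 (0.44) and PA2914 (0.61), of which np20 encodes Zur itself. The count of rises was 1 with any single library left out, 2 with upper-quartile factors and 0 with library totals alone. Camera gave the list an adjusted p of 0.00164, which was an adjusted p = 0.866 with an estimated correlation, and adjusted over the list alone 15 fell and 4 rose.

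Most metal efflux and copper genes did not pass the test, as held for all genes tested, of which 36.4% were called. Of 8 genes for zinc, cadmium and cobalt efflux, 2 rose and 6 did not pass the test. Those that rose were the sensor gene PA2524 (0.52) and its partner PA2523 (0.74, named after its value was seen), while the pump gene czcA had a value of -0.22 and an adjusted p of 0.247. PA2524 lost its call with library totals alone (adjusted p 0.288), without untreated replicate 1 (0.101), without treated replicate 1 (0.10) and without treated replicate 2 (0.0623). PA2523 lost its call with any single library left out (0.0746 to 0.128), and 0 of the list rose with library totals alone. Of 13 copper response genes, 3 rose, 1 fell and 9 did not pass the test. The copper exporter gene PA3920 (1.08 ± 0.14 SE), PA3521 (0.92) and the copper-uptake porin gene oprC (0.76 ± 0.14) rose. PA3520 (-1.80), counted at only 8.43 ± 4.17 and 2.41 ± 0.333 normalised CPM (n = 2), fell, but lost its call at -1.18 without untreated replicate 1 (adjusted p 0.0772) and at -1.67 without treated replicate 1 (adjusted p 0.0539). PA3521 had an adjusted p of 0.133 without treated replicate 2 and 0.0695 with library totals alone. Neither list was called by camera (adjusted p 0.627 and 0.756), the copper list had a median of -0.09 with a test direction of higher, and adjusted over the list alone the counts were 2 and 0, and 3 and 1.

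Most genes for taking up scarce sulfur and phosphate fell. Of 21 sulfur starvation genes, 13 fell, 1 rose and 7 did not pass the test, with a median log2 fold change of -0.53. The sulfate-binding protein gene sbp went from 191 ± 19.7 to 54.4 ± 0.644 normalised CPM (mean ± SD, n = 2), and PA3446 (-1.95), PA3445 (-1.66) and PA3938 (-1.47), of sulfonate and taurine uptake clusters, fell too. PA3442 (0.58), named after its value was seen, was the 1 that rose, and 0 rose with any single library left out, with upper-quartile factors or with library totals alone. Of 14 phosphate starvation genes, 11 fell, 0 rose and 3 did not pass the test, with a median of -0.54. These included the phosphate-binding protein gene pstS (-0.81 ± 0.12 SE), the permease gene pstC (-0.74 ± 0.11) and the porin gene oprP (-0.93 ± 0.20).

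The sulfur list had an adjusted p of 2.90e-10 by camera and an adjusted p = 0.528 with an estimated correlation. For the phosphate list camera gave an adjusted p of 4.96e-04, with an adjusted p = 0.866 with an estimated correlation. With p adjusted over the list alone, 14 sulfur genes fell and 1 rose, and 11 phosphate genes fell. Without treated replicate 1, 6 phosphate genes were called lower.

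Most heat shock genes rose. Of 16 genes for heat shock and protein quality control, 12 rose, 0 fell and 4 did not pass the test, with a median log2 fold change of 1.08. The small heat shock protein gene ibpA went from 59.9 ± 24.2 to 238 ± 41.5 normalised CPM (mean ± SD, n = 2), and the disaggregase gene clpB (1.42 ± 0.14 SE), the protease gene hslV (1.40 ± 0.13) and the co-chaperone gene dnaJ (1.10 ± 0.11) rose. The list had an adjusted p of 3.95e-12 by camera and an adjusted p = 0.850 with an estimated correlation, and 12 genes rose adjusted over the list alone. Of 8 envelope stress genes of the sigma factor AlgU, 0 passed edgeR's test and 0 did adjusted over the list alone, against 2 at an unadjusted p under 0.05, 1 with DESeq2, 3 with upper-quartile factors and 0 with limma-voom. The lowest p in that list was that of mucB, with a log2 fold change of 0.29, which was called without treated replicate 2 (adjusted p 0.0472) and with upper-quartile factors (0.0303). The list was not called by camera (adjusted p 0.722).

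Genes that modify lipid A rose more often than they fell. Of 23 genes for lipid A modification and the response to cationic peptides, 12 rose, 4 fell and 7 did not pass the test, with a median log2 fold change of 0.44. arnE (1.40 ± 0.13 SE), arnD (0.93 ± 0.11), arnT (0.73 ± 0.13) and arnB (0.70 ± 0.14), which add aminoarabinose to lipid A, rose. The outer membrane protein gene oprH went from 6068 ± 188 to 8704 ± 427 normalised CPM (mean ± SD, n = 2). Its adjusted p was 0.0276, and it was above 0.05 with any single library left out, from 0.0638 without treated replicate 2 to 0.415 without untreated replicate 1. The 4 that fell, named after their values were seen, were parR (-0.66), PA1797 (-0.57), parS (-0.55) and mgtA (-0.53), of which parS lost its call without treated replicate 1 (adjusted p 0.0733).

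The lipid A list had an adjusted p of 0.0326 by camera and an adjusted p = 0.866 with an estimated correlation. That call was lost without untreated replicate 2 (adjusted p 0.108, 6 higher) and without treated replicate 1 (adjusted p 0.0821, 6 higher). There were 12 rises and 6 falls adjusted over the list alone.

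Oxidative stress and drug efflux genes were mixed. Of 16 oxidative stress genes, 3 rose, 3 fell and 10 did not pass the test, among them the catalase genes katA (1.01 ± 0.14 SE), which rose, and katB (-0.62 ± 0.14), which fell. The call of katB was lost at -0.54 without treated replicate 1 (adjusted p 0.0516). Of 21 multidrug efflux genes, 5 rose, 5 fell and 11 did not pass the test. oprM (0.58), the outer membrane channel of the MexAB pump, rose and PA4375 (-0.69) fell. With a library left out, efflux genes gave 2 to 3 rises and 1 to 2 falls, and with library totals alone 1 rise and 2 falls, while DESeq2 gave 2 falls. The oxidative list gave 1 rise without untreated replicate 2, 1 rise and 1 fall without treated replicate 1, and 2 rises without treated replicate 2. Neither list was called by camera (adjusted p 0.821 and 0.861), and adjusted over the list alone 3 rose and 4 fell in the oxidative list and 5 rose and 5 fell in the efflux list.

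The flagellar genes that passed the test rose, by small amounts. Of 47 genes for flagella and chemotaxis, 22 rose, 0 fell and 25 did not pass the test, with a median log2 fold change of 0.27. The regulators flhF (0.63 ± 0.11 SE) and fleR (0.59), with PA1441 (0.64 ± 0.10) and PA1459 (0.57), had the lowest p in the list. Of 27 type IV pilus genes, 10 rose, 2 fell and 15 did not pass the test, with chpA (0.93 ± 0.14), a sensor kinase gene for twitching, going from 432 ± 1.09 to 823 ± 17.1 normalised CPM (mean ± SD, n = 2). The 2 that fell, named after their values were seen, were the motor genes pilB and pilT, each with a log2 fold change of -0.28. With any single library left out, 0 pilus genes were called lower, and without treated replicate 1 the count of rises was 3.

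The flagella list had an adjusted p of 9.60e-04 by camera and an adjusted p = 0.866 with an estimated correlation. Its count of rises was 7 without treated replicate 1 or with library totals alone, 11 without untreated replicate 2 and 13 without untreated replicate 1. The type IV pilus list was not called (adjusted p 0.139), but was without untreated replicate 1 (0.0373) and without treated replicate 2 (0.0342). Adjusted over the list alone, 23 flagellar genes rose, and 11 pilus genes rose and 2 fell.

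The quorum-sensing and secreted virulence genes that passed the test fell. Of 31 genes, 12 fell, 0 rose and 19 did not pass the test, with a median log2 fold change of -0.36. The hemolytic phospholipase gene plcH went from 57.9 ± 0.931 to 36.9 ± 2.85 normalised CPM (mean ± SD, n = 2), the lectin gene lecA (-1.89 ± 0.42 SE) fell at a low level of 7.58 ± 2.77, and the elastase gene lasB (-0.58 ± 0.15) fell, with its call lost at -0.47 without treated replicate 1 (adjusted p 0.0839). Of 21 phenazine genes, 5 fell, 2 rose and 14 did not pass the test. phzB1 (-1.99 ± 0.39) and phzA1 (-1.25) fell, but lost their calls at -1.04 and -0.86 without untreated replicate 1 (adjusted p 0.0989 and 0.0979) and at -1.65 and -1.13 without treated replicate 1 (adjusted p 0.0857 and 0.0629), and the pump channel gene opmD (1.28 ± 0.24) rose. The phz1 and phz2 operons are near-identical copies, so their split of reads is uncertain. Falls in the phenazine list numbered 1 without untreated replicate 1 and 0 without treated replicate 1, and rises numbered 1 without either untreated library, without treated replicate 2, with upper-quartile factors, with library totals alone, with a minimum of 10 CPM or with limma-voom.

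Of 33 exopolysaccharide genes, 8 fell, 6 rose and 19 did not pass the test, with algD (-1.07 ± 0.20 SE) of alginate synthesis falling and pslF (0.81 ± 0.11) and pslH (0.64) of Psl synthesis rising. Rises numbered 3 with any single library left out, 3 with upper-quartile factors and 2 with library totals alone, and falls numbered 3 without untreated replicate 1, 2 without treated replicate 1 and 5 with library totals alone. The quorum-sensing list had an adjusted p of 0.0349 by camera and an adjusted p = 0.886 with an estimated correlation. The call was lost with library totals alone (adjusted p 0.0759), with a minimum of 10 CPM in 2 libraries (0.0643), without untreated replicate 2 (0.143) and without treated replicate 1 (0.142), which left 2 genes called lower. Neither the phenazine nor the exopolysaccharide list was called (adjusted p 0.627 and 0.713). Adjusted over the list alone, 12 quorum-sensing genes fell, 5 phenazine genes fell and 1 rose, and 9 exopolysaccharide genes fell and 6 rose.

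Genes of the filamentous prophage Pf and of pyocins, the phage-tail-like and soluble bacteriocins of this species, fell where they passed the test. Of 14 Pf genes, 10 fell, 0 rose and 4 did not pass the test, with a median log2 fold change of -0.65. PA0724 (-1.08 ± 0.15 SE) and PA0727 (-1.31 ± 0.21) were among them. Of 42 genes for the SOS response and pyocins, 18 fell, 0 rose and 24 did not pass the test, with a median of -0.28, and the soluble pyocin gene pyoS5 went from 102 ± 15.6 to 57.6 ± 1.79 normalised CPM (mean ± SD, n = 2). The untreated libraries differed for these genes, since 52 of the 56 were higher in untreated replicate 1, the library with 15.3% ribosomal RNA, than in untreated replicate 2. Their median was -0.36 with all libraries, -0.18 without untreated replicate 1, -0.52 without untreated replicate 2, and -0.36 without either treated library.

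Camera gave the Pf list an adjusted p of 2.39e-04, with an adjusted p = 0.866 with an estimated correlation, and the SOS and pyocin list an adjusted p of 7.14e-04, again with an adjusted p = 0.866 with an estimated correlation. Counts of Pf genes called lower were 4 without untreated replicate 1, 3 without treated replicate 1 and 6 without treated replicate 2, and those of the SOS and pyocin list were 3, 3 and 4. With library totals alone they were 6 and 11. The call of PA0727 was lost without untreated replicate 1 (log2 fold change -0.70, adjusted p 0.0545) and without treated replicate 1 (adjusted p 0.0519). With p adjusted over the list alone, 11 Pf genes and 19 SOS and pyocin genes fell.

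Of 54 ribosomal protein genes, 2 rose, 1 fell and 51 did not pass the test, and adjusted over the list alone 0 rose and 0 fell, against 6 at an unadjusted p under 0.05 and 6 called over all genes by DESeq2. Among them rpsS (0.42) rose and rpsT (-0.39) fell, but rpsS lost its call without untreated replicate 2 (adjusted p 0.38) and without treated replicate 1 (0.298), and rpsT with any single library left out (0.0677 to 0.469).

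Of 41 genes for the respiratory chain and ATP synthase, 6 rose, 3 fell and 32 did not pass the test. The median log2 fold change was 0.17. The oxidase gene ccoO2 (0.71 ± 0.13 SE) rose, while the aa3-type oxidase gene coxA (-0.95 ± 0.15) and the ATP synthase accessory gene atpI (-0.80 ± 0.12) fell. Rises in that list numbered 0 without treated replicate 1 and 1 without untreated replicate 2. Of 13 citric acid cycle genes, 2 rose and 11 did not pass the test, with the aconitase gene acnA going from 347 ± 10.7 to 825 ± 74.3 normalised CPM (mean ± SD, n = 2). Of 21 genes for peptidoglycan synthesis and cell division, 8 rose, 3 fell and 10 did not pass the test, with murC (0.64 ± 0.13) and murG (0.62) rising. Their rises numbered 3 without treated replicate 1 and 5 without untreated replicate 2, and their falls 1 without untreated replicate 2 or either treated library. In the citric acid cycle list 1 rose without treated replicate 1, and 4 did with upper-quartile factors or DESeq2.

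Of 6 stationary phase genes, the ribosome hibernation factor gene rmf (1.47 ± 0.12 SE) and its partner PA4463 (0.64 ± 0.14) rose, and the sigma factor gene rpoS (-0.44 ± 0.11) fell, with its call lost at -0.36 without untreated replicate 1 (adjusted p 0.0609). None of these 5 lists was called by camera (adjusted p 0.627 for ribosomal proteins, 0.293 for respiration, 0.269 for the citric acid cycle, 0.244 for peptidoglycan and 0.337 for stationary phase). The respiratory list was called without untreated replicate 1 (0.0176) and the peptidoglycan list without treated replicate 2 (0.0317). Adjusted over the list alone, respiratory genes gave 6 rises and 3 falls, citric acid cycle genes 2 and 0, peptidoglycan genes 8 and 3, and stationary phase genes 2 and 2.

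**Figure D2:**
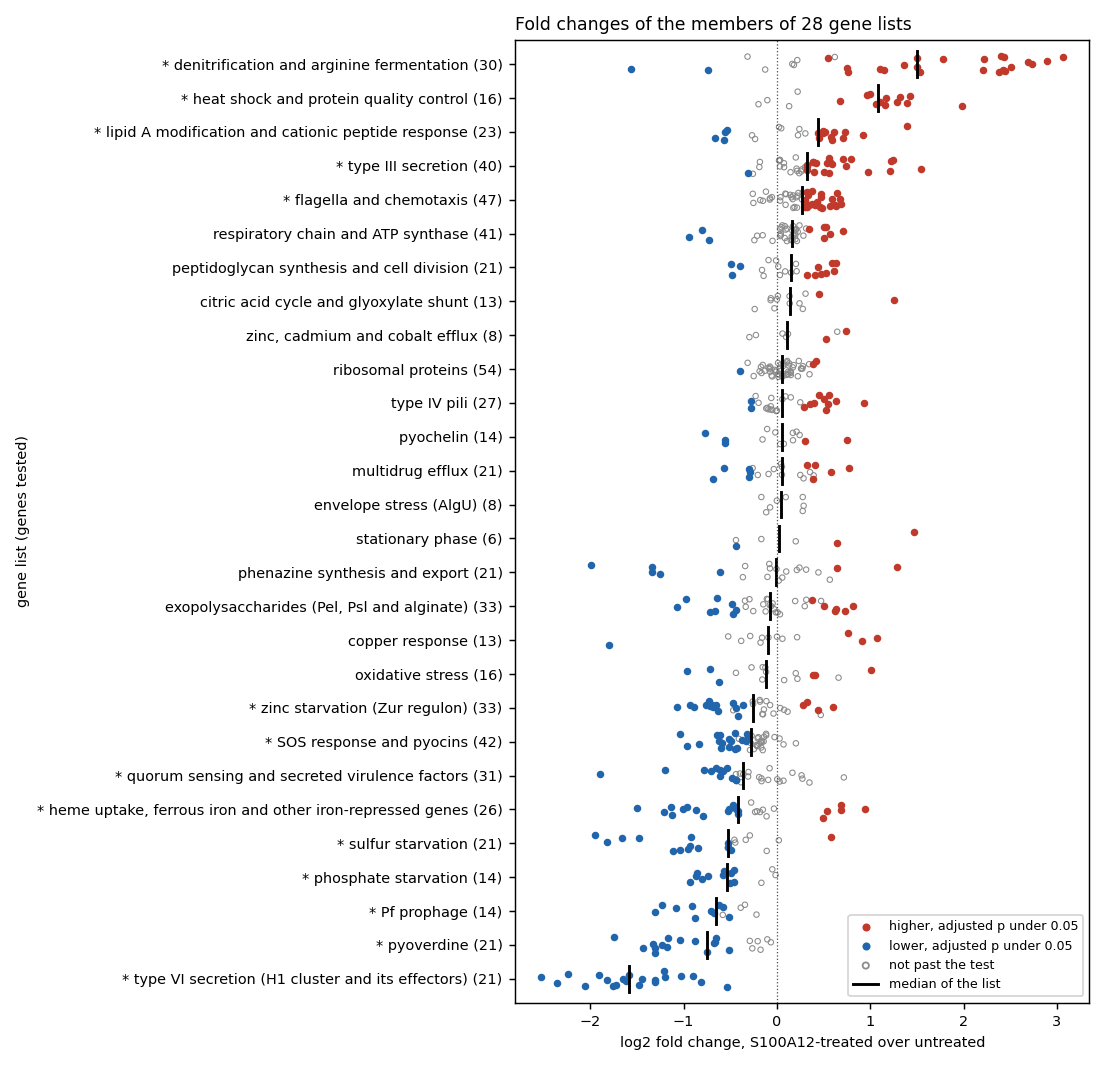
Log2 fold change, S100A12-treated over untreated, of each member (point) of the 28 gene lists, with filled points for genes past an adjusted p of 0.05, a bar at each list's median, the number tested in brackets and an asterisk for the 14 lists called by camera. Medians run from -1.58 for type VI secretion to 1.5 for denitrification and arginine fermentation, and those of phenazine, type IV pilus, multidrug efflux, AlgU, ribosomal and stationary phase genes change sign with the scaling.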

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

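Among the genes named by the fixed rule and the called lists, no alternative reversed a direction where the main fit or the alternative made a call. These alternatives were planned, and sign changes of genes called in neither fit were not counted. narG, named after its values were seen and not called, went from 0.22 to -0.18 without treated replicate 2. Of the 2064 called genes, 4 changed sign without untreated replicate 1. Of 1505 values of genes named by the rule under alternatives, 1440 kept their side of the threshold, 55 lost the call and 10 gained it. Direction was compared only for values called in the main fit or the alternative. Counts of calls were 1142 (452 higher, 690 lower) with library totals, 690 lower at an adjusted p of 0.01, and 349 (156 higher, 193 lower) with a 2-fold minimum. With a library left out they were 965 to 1540 in all, 574 to 756 higher and 391 to 784 lower. Those fits hold fewer samples, and other causes were not tested. The labels share replicate numbers but do not say whether these pair the cultures. Same-numbered libraries tended to deviate together (correlation of replicate differences 0.40 across genes). With 2 pairs this cannot decide whether the cultures were paired, and the main test used no pairing. With the replicate block 2935 genes were called, and no list gained or lost its call, while mucB (adjusted p 0.0056) and 3 AlgU genes in all gained one. With an estimated correlation 0 lists were called and with fry 1, denitrification and arginine fermentation (adjusted p 0.0387). Adjusted p with an estimated correlation was 0.866 for zinc, heme and iron, type III, flagella, lipid A, phosphate, SOS and Pf, 0.528 for pyoverdine, type VI and sulfur, 0.886 for quorum sensing, 0.850 for heat shock and 0.486 for denitrification. With fry it was 0.118 for zinc and phosphate, 0.0602 for pyoverdine, 0.175 for heme and iron, type III and lipid A, 0.233 for quorum sensing, 0.0858 for type VI and sulfur, 0.142 for flagella, 0.113 for heat shock and 0.255 for SOS and Pf. The quorum-sensing list had 0.0759 with library totals, 0.0643 with the minimum of 10 CPM and 0.00525 to 0.143 with a library left out, and the lipid A list 0.00377 to 0.108. Members called with library totals were 6 lower for quorum sensing, 13 higher for type III, 7 higher for flagella, 11 lower for SOS and 6 lower for Pf. With a library left out the members called were 8 to 13 lower for heme and iron, 2 to 10 lower for quorum sensing, 12 to 18 higher for type III, 7 to 18 higher for flagella, 6 to 10 higher for lipid A, 6 to 10 lower for phosphate, 3 to 20 lower for SOS and 3 to 13 lower for Pf. The causes of these losses were not tested. No gene had fewer than 23 counts in a library, and whether depth limits the calls of low genes was not tested.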

Other observations

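Tests of base composition, of a single library for type III secretion, of withheld zinc, of neighbouring genes and of the cob family were chosen only after the result was seen, as were the genes and families named here beyond the fixed lists. Cobalamin synthesis genes were the family outside the lists with the lowest p for rises. Of 15 genes whose symbols start with cob, 11 rose and 0 fell, with a median log2 fold change of 0.60 and, among them, cobU at 1.22 ± 0.22 (SE) and cobL at 1.13 ± 0.17. Fisher's exact test against 1763 genes with a family name gave an adjusted p of 0.00328 over 99 families and both directions, although neighbours in an operon are not independent. The count of rises was 8 with upper-quartile factors, 3 with library totals alone, and 5 to 8 with a library left out, lowest without treated replicate 2. Runs of neighbours that rose included PA3181 to PA3185, with pgl (1.76) and zwf (0.85), at a mean log2 fold change of 0.95, PA3191 to PA3195, with glk (1.01) and edd (0.82), at 0.80, and fdnG, fdnH and fdnI with selA and selB, at 0.88. No pathway was tested for these runs. In all, 89 runs of at least 4 neighbouring protein-coding genes were called in 1 direction, 46 higher and 43 lower, against a highest count of 22 in 1000 shuffles, but shuffling treats genes as independent and neighbours in an operon share a transcript, so this comparison decides nothing.

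Among families that fell, 9 of 15 wbp genes of O-antigen synthesis (median -0.36, adjusted p 0.00328) and 7 of 14 cup genes of fimbriae (median -0.39, adjusted p 0.0346) were called lower by the same Fisher test, with 3 to 7 and 2 to 7 when a library was left out. Wbp calls were 3 without treated replicate 2, 4 without treated replicate 1 and 5 without untreated replicate 1, and cup calls were 2 without treated replicate 1, where the median was -0.19, and 4 without untreated replicate 1 or with library totals alone. Runs of PA1381 to PA1393 (13 genes, mean log2 fold change -1.33) and PA2221 to PA2228 (8 genes, -1.27) fell, with means of -0.72 and -0.61 and 5 and 1 genes called without untreated replicate 1. The median log2 ratio of untreated replicate 1 to 2 was 0.26 for the wbp genes and -0.07 for the cup genes. Without untreated replicate 1 the wbp median was -0.28. For the runs of PA1381 to PA1393 and PA2221 to PA2228 that ratio was 1.10 and 1.12. Without treated replicate 1 they had 5 and 3 genes called, and PA2221 to PA2228 had 3 without treated replicate 2. By RNA class, 31 of 63 tRNA genes fell and 0 rose, with a median of -0.55, against 9 falls and 2 rises without untreated replicate 1, 12 falls without treated replicate 1 and 10 falls and 2 rises without treated replicate 2. Of 13 genes annotated as rRNA, 8 fell, but for 4 of these the treated libraries lay between the untreated ones, and without untreated replicate 1 the median went from -0.96 to 0.95 with 4 rises and 2 falls. The tmRNA (0.84) and RNase P RNA (0.89) rose, but the tmRNA was not called without untreated replicate 1, untreated replicate 2 or treated replicate 1 (1.06, 0.67 and 0.66), nor the RNase P RNA without untreated replicate 2 or treated replicate 1 (0.49 and 0.61).

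Pf prophage and pyocin genes were lower with S100A12, but 52 of 56 were also higher in untreated replicate 1 than in 2. Leaving out untreated replicate 1 gave 25% as many falls and took the median from -0.36 to -0.18, with 51 of 56 still negative, while leaving out either treated library also cut the calls but left the median at -0.36, so part of the fall rests on untreated replicate 1 and the source of the rest cannot be told apart. A weaker SOS response had little to show for it, with a median of -0.13 over recA, lexA, sulA and recN and 0 of 4 called lower, yet that value is too near the stated bound to exclude it. Base composition may be involved, as the untreated libraries differed by 0.29 (log2) over these genes relative to all genes, but no genome was used here to test it. An effect of the treatment itself stays open and untested beyond these values.

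Lower type VI and higher type III secretion may follow from less RsmY and RsmZ, small RNAs that sequester the regulator RsmA. For type VI the data argue against a single library as the cause. The run of PA0074 to PA0095, which holds the H1 cluster, kept mean log2 fold changes of -1.37 to -1.64 with a library left out. For type III that test was chosen after its values were seen. Fewer type III members passed with a library left out, so the test decides nothing there. rsmY had a log2 fold change of -0.94 (adjusted p 0.0337 by edgeR, but 0.307 without untreated replicate 1 and 0.162 without treated replicate 1) and rsmZ of -0.90 (adjusted p 0.0596). Both are short and sparsely counted, at 8.94 and 7.23 CPM in untreated cultures, and 28 noncoding RNA genes had a median of -0.39 with 6 lower and 2 higher. A drop of these regulators and a lower recovery of short RNAs, a class in which the tmRNA and RNase P RNA went the other way, cannot be told apart here.

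Of the zinc-repressed and of the heme and iron genes, more fell than rose with S100A12, a protein that binds zinc, with 14 falls of 33 genes and 14 of 26. Zinc withheld from the treated cells would raise the Zur list, whose median was -0.26 with 4 rises, so these values argue against it at this time point. They are the pattern itself, so this was not a separate test. The zinc-binding protein gene znuA showed no difference (0.08, adjusted p 0.589 by edgeR), and with an estimated correlation camera did not call the list (adjusted p 0.866). More available iron is a candidate explanation for the iron part, since bfrB, an iron-storage gene that rises with iron, was higher by 1.01 (adjusted p 7.46e-09 by edgeR, and 0.79 to 1.22 on the log2 scale with a library left out) and the iron-repressed small RNAs prrF1 (-1.43) and prrF2 (-1.24) were lower. Other values go the other way or are weak, since the Feo genes PA4357, PA4358 and PA4359 with exbB1 and exbD1 rose, the pyochelin list was not called (median 0.06, adjusted p 0.948), and prrF1, a short RNA, lost its call without untreated replicate 1 (adjusted p 0.0874) and without treated replicate 1 (0.0711). Where such iron could come from, including metal carried by the protein preparation or the change to anaerobic gene expression, was not tested.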
